A study of Mus musculus with 8 samples.

How the data were processed

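RNA was measured by sequencing in tail epidermis of 8 mice aged 8 weeks, 1 library per mouse. Per the labels' protocols, tail skin was kept in 10 mg/ml dispase for 5 h at 4 °C and the epidermis was then peeled from the dermis. Stranded poly-A libraries were made from 1 microgram of total RNA and read as single 75 bp reads on a NextSeq instrument. No cell sorting is mentioned in the labels, so the sheet could hold any cell type attached to the epidermis, hair follicles included.

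The deposited values were raw read counts per gene for 46983 Ensembl gene identifiers, with no normalization, as the values themselves showed (whole numbers with a different sum in each library). Per the submitters' processing notes, the tools included cutadapt 1.7.1, Bowtie2 2.2.4, STAR 2.4.1d, SAMtools 1.1, Cufflinks 2.1.1, bedtools 2.17.0, featureCounts 1.4.6 and edgeR 3.8.6, and the genome build was GRCm38. The annotation release, the strand setting of the counting and the treatment of reads with several matches were not given in the sources used here. Reads from overlapping genes, and from families of near-identical genes such as Krtap, Sprr2, Lce3, Skint and MHC genes, could therefore be split or lost, and values of single members of these families are uncertain.

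Gene symbols, positions and GC content came from GENCODE mouse release M21, which uses the same build, and 46488 of the identifiers were found there. Each column of the count table was matched to its mouse by the mouse identifier in the labels. The labels gave the genotype of every mouse. The 4 CTR mice carried the K14-Cre transgene, which is active in basal keratinocytes, with 1 floxed and 1 wild-type Ppp1r8 allele. The 4 SKO mice carried the same transgene with 1 floxed allele and 1 allele written as null. Replicate numbers followed the order of the samples and only name libraries, so no libraries were paired. Each CTR mouse identifier lies next to an SKO identifier, but a fit with such neighbours as pairs was not run. The labels gave neither the sex nor the litter of the mice.

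Library totals ranged from 16696212 to 21571935 counts, so that 3 counts in a library corresponded to 0.139 to 0.180 CPM, taken as the floor of detection, or to 0.0388 CPM over the 4 SKO libraries together. Floors and counting intervals cover counting error only, since reads were not marked with molecular identifiers. Libraries of a group were compared pair by pair, and no pair agreed within sampling noise.

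Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) on all 8 libraries with group as the only term. Normalization was by trimmed mean of M values, and filterByExpr at its default settings kept 15638 genes. Benjamini-Hochberg adjustment ran over these genes, with a threshold of 0.05. Adjusted p-values of genes below come from this test. Values per library are normalised CPM, and group values are means ± SD. In simulated counts for the 15638 genes of this comparison, the script recovered 4% of 50 genes changed by 1.25-fold, 46% of 50 changed by 1.5-fold, 72% of 50 changed by 2-fold and 98% of 50 changed by 4-fold, and 7 of 129 calls (5.43%) were false. The simulation changed few genes and gave 129 calls, against 3700 in the data. Its cutoff on unadjusted p was therefore stricter, and the recovered shares need not hold for the data. Small changes can still be missed at this number of libraries.

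Gene lists for pathways, skin cell states and other cell types were fixed, 51 in all, of which 46 had at least 5 tested genes and could be tested (63 genes stood in more than 1 list). Each was tested on log2 CPM values with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. The same test was run with the correlation estimated per list. The rotation test fry was run beside it. Its PValue tests whether a list's genes move, on balance, one way, and PValue.Mixed whether they change in either direction, and neither compares the list with other genes. Library totals, shares of counts and mean log2 CPM of lists for other cell types were compared by two-sided exact permutation tests over the 70 assignments of libraries to groups, where the smallest p possible is 0.0286, with Benjamini-Hochberg adjustment over the 19 measures (scipy 1.17.1).

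Groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined, except that the shares of mitochondrial and Krtap counts and the tests of explanations in the closing part were added later. The rule took Ppp1r8, the 10 largest rises and 10 largest falls among changed genes with a mean of at least 1 CPM, groups without overlap and a symbol that is not a clone name, the 5 genes with the smallest p, and from each list up to 4 changed members with the largest change at a mean of at least 1 CPM, filled up to 2 with the most abundant members where fewer changed. Not all of these genes are described. Ranges of list values over alternatives are those of camera at the preset correlation. They leave out the estimated correlation and fry, which are given separately. Alternatives covered 3 other normalizations (DESeq2 1.42.0 size factors, library totals, upper quartile), no filter on low counts or a stricter one (5 CPM in 4 libraries), the DESeq2 test, the edgeR likelihood-ratio test, limma-voom, a robust fit, Xist level, series of mouse identifiers or GC content as further terms, other thresholds, and leaving out each library in turn.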

Results

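The study addressed what NIPP1, a nuclear regulator of protein phosphatase PP1 encoded by Ppp1r8, does in the epidermis. Sequenced RNA came from the tail epidermis of 8 mice, 4 in each group. CTR mice carried a keratinocyte Cre transgene with 1 floxed and 1 wild-type Ppp1r8 allele. SKO mice carried the same transgene with 1 floxed and 1 null allele. Total counts of CTR 1 to 4 were 19382156, 20599891, 16696212 and 21571935. Those of SKO 1 to 4 were 18649079, 19205490, 20500885 and 18932667. The totals did not differ by more than the spread within groups (exact permutation p = 0.800, n = 4 per group). The first principal component held 61.8% of the variance and had all CTR libraries on one side and all SKO libraries on the other. Correlations of log2 CPM between libraries were 0.972 to 0.990 within groups and 0.930 to 0.974 between groups.

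Ppp1r8 itself (ENSMUSG00000028882.13, chromosome 4, 132826929 to 132843169, GRCm38) did not differ detectably in its gene-level counts. Its level was 37.9 ± 3.58 CPM in CTR and 36.4 ± 8.00 CPM in SKO (SD, n = 4 each), a log2 fold change of -0.06 (SE 0.14, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.789). CTR libraries lay between 34.7 and 41.6 CPM and SKO libraries between 28.4 and 47.4 CPM. Without SKO 2 the log2 fold change was 0.05. The count sums reads over all exons, and the part of the gene removed by Cre was not given in the sources used here. This value therefore does not check the genotype labels, which were used as given. Of 13 tested genes for PP1 catalytic subunits, nuclear PP1 regulators and NIPP1 partners, Cdc5l, a NIPP1-binding splicing factor, rose by 1.29-fold (adjusted p = 0.0254). Ppp1cc, the PP1 gamma subunit gene, was 1.32-fold lower (adjusted p = 0.0166), and 1 gene up and 1 down were also called adjusted over the list alone. The Ppp1cc call ended without SKO 2 (adjusted p = 0.0504), and the Cdc5l call ended without CTR 2, CTR 3, CTR 4 or SKO 4 (adjusted p = 0.0570 to 0.0681). The list as a whole was not past the threshold (camera adjusted p = 0.904).

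SKO epidermis had higher levels of many chemokine and alarmin genes, and lower levels of most hair shaft genes and of some hedgehog and Wnt feedback genes. Of 15638 genes tested, 3700 changed, 1792 of them higher and 1908 lower in SKO. Among these, 1006 changed by at least 2-fold, 378 higher and 628 lower. Among the largest rises were Ccl2, which attracts monocytes (47.2-fold, from 0.361 ± 0.189 to 16.8 ± 9.39 CPM, adjusted p = 0.000235), Ccl1 (26.0-fold, adjusted p = 0.000126) and Ccl20, a ligand of the receptor CCR6 (17.2-fold, adjusted p = 0.000595). Cdkn2a, the locus of the cell cycle inhibitor INK4A and of ARF, rose from 0.0999 ± 0.0643 to 4.13 ± 4.18 CPM (38.0-fold, adjusted p = 0.00307). The beta-defensin gene Defb5 rose by 35.1-fold, the peptidoglycan amidase gene Pglyrp2 by 17.6-fold and the keratinocyte cytokine gene Tslp by 12.2-fold. These rises start from low CTR levels: Cdkn2a and Defb5 each had 8 counts over the 4 CTR libraries, Tslp 14, Ccl1 17 and Ccl2 27. The largest falls were those of Skint3, Skint4 and Skint9, members of a chromosome 4 family of immunoglobulin-like genes of the epidermis. Skint3 had 21.7 ± 4.93 CPM in CTR and 0 counts in all SKO libraries. This was 551-fold lower against a floor of 3 counts over the SKO group (lower 95% counting limit 447.5-fold, adjusted p = 7.59e-05). Skint9 likewise went from 9.76 ± 2.60 CPM to 0 counts, 248-fold lower against that floor (lower 95% counting limit 200.9-fold, adjusted p = 0.000157). Skint4 went from 19.7 ± 4.26 CPM to 1 count in SKO, a ratio of 1492 with a 95% counting interval of 267.5 to 58990 (adjusted p = 2.33e-06). Others among the largest falls were the matrix proteoglycan gene Ogn (from 11.3 ± 2.04 to 0.453 ± 0.293 CPM, 24.6-fold lower, adjusted p = 7.65e-05) and the hedgehog antagonist gene Hhip (from 31.1 ± 14.0 to 1.36 ± 0.772 CPM, 22.8-fold lower, adjusted p = 0.000271). So were 5 hair keratin-associated protein genes, Krtap5-1, Krtap31-2, Krtap5-4, Krtap5-2 and Krtap28-13, which were 16.0- to 22.9-fold lower. The 5 smallest p-values were those of Skint4, Pglyrp2, Gm10288, Cpxm2 and Zfp618. The last 3 were 5.53-fold, 6.15-fold and 4.63-fold lower in SKO. The groups did not overlap for 4094 of all tested genes (26.18%, against 2.86% by chance). With the level of Xist as a further term, 80 genes changed. Of 122 called genes named in this text and checked with that term, 17 kept their call: Ccl1, Ccl2, Krt6b, Pglyrp2, Skint3, Skint4, Skint9, Ogn, Gm10288, Cpxm2, Zfp618, Krt1, Ly6a, Nlrc5, Tnfaip2, Eda2r and Ereg. The log2 fold changes of Defb5, Ccl20 and Tslp were then 2.62, 2.03 and 2.62, in place of 5.14, 4.11 and 3.61, and that of Cdkn2a was 6.86, with 0 of these 4 calls kept. Xist itself was lower in SKO (792 ± 153 and 419 ± 114 CPM, adjusted p = 0.00817). Without SKO 2 the Cdkn2a log2 fold change was 4.25 in place of 5.25. Without SKO 4 those of Defb5 and Tslp were 4.47 and 3.0 in place of 5.14 and 3.61. Without SKO 3 the falls of Krtap5-1, Krtap5-2, Krtap5-4 and Krtap28-13 were larger (-5.48, -4.67, -4.86 and -4.59).

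**Figure D1:**
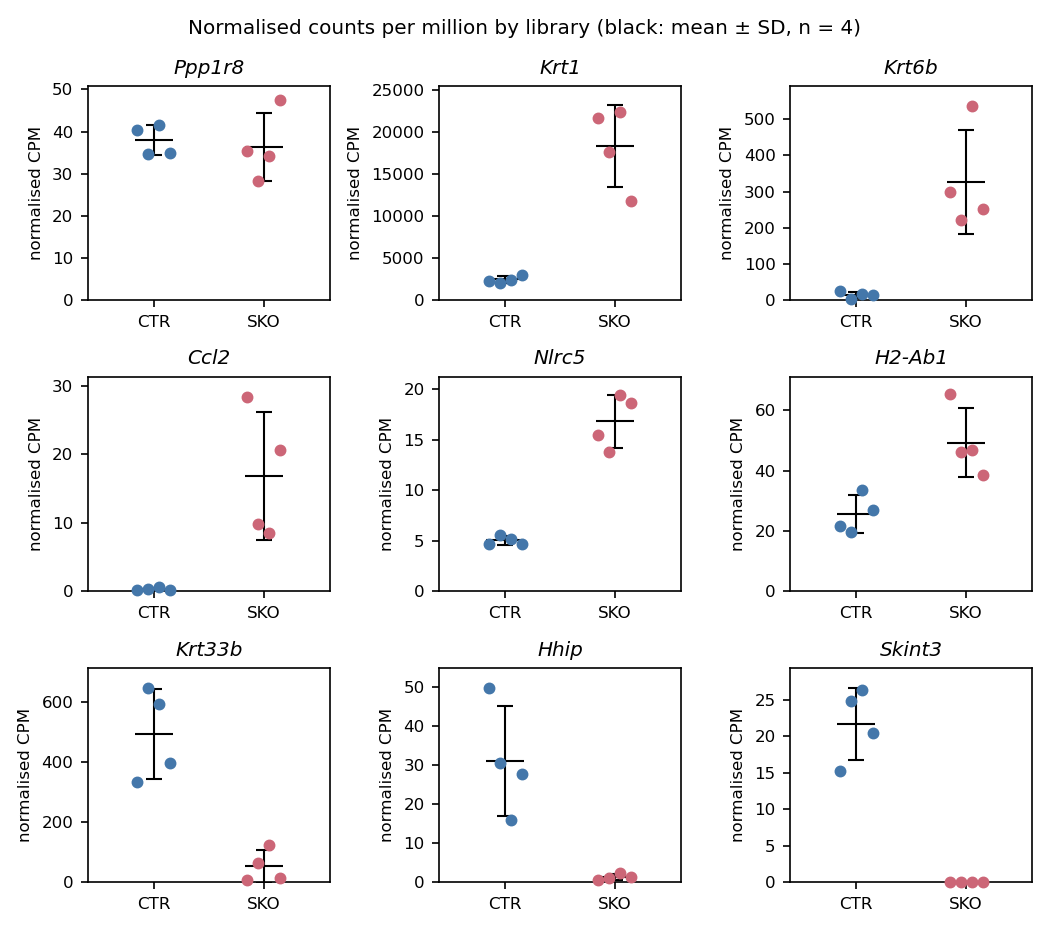
Normalised CPM of 9 genes in each of the 4 CTR and 4 SKO libraries (points), with the group mean and SD in black, on linear axes that start at 0. The groups overlap for Ppp1r8 and are separate for the other genes, such as Nlrc5 (5.03 ± 0.417 in CTR, 16.8 ± 2.64 in SKO).

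Several keratin genes were more abundant in SKO. Krt1, a spinous layer keratin, rose from 2488 ± 430.2 to 18366 ± 4854 CPM (log2 fold change 2.88, SE 0.21, adjusted p = 9.43e-05). Its partner Krt10 rose from 15650 ± 611 to 31131 ± 3704 CPM (0.99, SE 0.11, adjusted p = 0.000486). Krt6b, a keratin of wounded epidermis, rose 21.6-fold from 15.1 ± 8.28 to 327 ± 143 CPM (adjusted p = 0.000413). Of 24 hyperproliferation keratins and alarmins, 15 rose and 2 fell (16 and 2 adjusted over the list alone). The list was higher in SKO (camera adjusted p = 4.15e-06, adjusted p = 0.284 with an estimated correlation). S100a8 and S100a9, the subunits of calprotectin, rose 16.6-fold and 21.5-fold (adjusted p = 0.004 and 0.00483). Without SKO 4 their log2 fold changes were 3.45 and 3.66 in place of 4.06 and 4.43. The protease inhibitor gene Stfa2 rose 6.86-fold. Of 19 small proline-rich and LCE3 genes, which encode cornified envelope proteins of stressed epidermis, 9 rose and 0 fell (11 and 0 adjusted over the list alone). The median log2 fold change of the list was 1.41 (camera adjusted p = 1.7e-05, adjusted p = 0.438 with an estimated correlation). Lce3a, Lce3e and Lce3f rose 8.06-, 6.66- and 5.11-fold, from CTR levels of 0.222, 0.351 and 1.03 CPM. Granular layer and cornified envelope genes had 10 of 33 higher and 2 lower (12 and 3 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.574 with an estimated correlation). Among them the envelope protein gene Rptn rose 2.51-fold and the transglutaminase gene Tgm5 1.91-fold. Tchh, also of this list, fell 4.81-fold, from 2440 ± 700 to 507 ± 419 CPM (adjusted p = 0.0275). The list's call ended without SKO 3 (adjusted p = 0.0989, over alternatives 0.00038 to 0.0989). Of 20 spinous layer genes, only Krt1 and Krt10 rose and 2 fell, also adjusted over the list alone. The list's median (-0.08) and mean (0.10) differed in sign, and camera and fry gave opposite directions (camera adjusted p = 0.904).

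Some basal keratinocyte and junction genes were lower. Of 20 basal genes, 5 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0393, adjusted p = 0.438 with an estimated correlation). Krt15 fell from 2683 ± 88.7 to 1844 ± 176 CPM (adjusted p = 0.00293). The hemidesmosome integrin gene Itgb4 fell from 351 ± 47.4 to 189.6 ± 24.0 CPM (adjusted p = 0.00123) and Igfbp3 from 133 ± 48.2 to 46.2 ± 24.9 CPM (adjusted p = 0.0165). In the robust fit the Igfbp3 call ended (adjusted p = 0.0610, over alternatives up to 0.635). Ifitm3, a basal list gene, rose 1.63-fold (adjusted p = 0.0122). The basal list was not past the threshold without SKO 1 (adjusted p = 0.0916) or SKO 4 (0.0595), with 0.0214 to 0.900 over all alternatives. Of 20 tight junction, desmosome and gap junction genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone, camera adjusted p = 0.00565, adjusted p = 0.438 with an estimated correlation). The list's median log2 fold change was -0.18 and its mean -0.34. The desmosome gene Dsg4 fell from 64.6 ± 17.1 to 13.3 ± 12.5 CPM (log2 fold change -2.28, adjusted p = 0.022). In SKO 1 to 4 it had 2.46, 17.7, 28.9 and 4.08 CPM, in the same order as the hair keratin gene Krt33b (9.38, 65.5, 124 and 13.7 CPM). The connexin genes Gja1 and Gjb6 changed by -0.70 and -0.76 on the log2 scale (adjusted p = 0.00333 and 0.00439). EGFR ligand and feedback genes moved both ways, 4 higher and 2 lower of 20, also adjusted over the list alone (camera adjusted p = 0.68). The ligand genes Ereg and Hbegf and the phosphatase gene Dusp4 rose, by 0.84, 0.76 and 0.82 on the log2 scale.

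Many genes of antigen presentation and of inflammatory signalling were higher in SKO epidermis. Of 22 interferon-gamma response and MHC class I genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone). Their median log2 fold change was 1.08 (camera adjusted p = 6.77e-13, adjusted p = 0.284 with an estimated correlation). Nlrc5, the MHC class I transactivator, rose from 5.03 ± 0.417 to 16.8 ± 2.64 CPM (log2 fold change 1.74, adjusted p = 0.00015). The immunoproteasome genes Psmb8 and Psmb9 rose by 1.53 and 1.57 on the log2 scale (adjusted p = 0.000491 and 0.00312), and the guanylate-binding protein gene Gbp7 rose by 1.69. NF-kappaB targets had 17 of 21 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.7e-07, adjusted p = 0.284 with an estimated correlation). Tnfaip2 rose from 7.23 ± 0.451 to 20.2 ± 1.48 CPM (adjusted p = 6.87e-05), and the transcription factor gene Irf1 rose by 1.15 on the log2 scale. The neutrophil attractant gene Cxcl1 rose 7.14-fold (adjusted p = 0.00563), or by 2.19 on the log2 scale without SKO 4 and by 0.58 with the Xist term, in place of 2.84. Chemokine genes had 9 of 14 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 7.9e-05, adjusted p = 0.284 with an estimated correlation). Cytokine genes and their receptors had 8 of 16 higher and 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.284 with an estimated correlation). Lif was 3.71-fold higher (adjusted p = 0.00228). Type I interferon-stimulated genes had 7 of 17 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.00426, adjusted p = 0.327 with an estimated correlation). Parp14 was 2.44-fold higher. With the stricter count filter the chemokine, cytokine, proline-rich and interferon-stimulated lists were not past the threshold (adjusted p = 0.0605, 0.403, 0.05 and 0.05). Over alternatives the values of these lists were 3.1e-07 to 0.0605, 0.0012 to 0.403, 3.1e-07 to 0.05 and 0.000211 to 0.185. The highest value of the interferon-stimulated list came with Xist as a further term.

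Markers of immune cells also differed. Of 10 MHC class II genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00345, adjusted p = 0.438 with an estimated correlation). H2-Aa went from 25.4 ± 4.67 to 49.1 ± 9.18 CPM and H2-Ab1 from 25.5 ± 6.24 to 49.2 ± 11.4 CPM (adjusted p = 0.00311 and 0.00715). H2-Eb1 rose from 18.1 ± 4.50 to 37.0 ± 6.77 CPM and the invariant chain gene Cd74 rose 1.83-fold (adjusted p = 0.00398 and 0.00545). Langerhans and dendritic cell markers had 4 of 10 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.00909, adjusted p = 0.438 with an estimated correlation). Cd207, the gene of langerin, rose from 4.34 ± 0.668 to 7.51 ± 1.55 CPM (adjusted p = 0.0109), Itgax 2.03-fold and Mfge8 1.49-fold. T and natural killer cell markers had 4 of 7 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0406, adjusted p = 0.438 with an estimated correlation). The T cell receptor gene Trbc2 rose from 8.79 ± 2.18 to 16.2 ± 4.30 CPM (adjusted p = 0.0174). Thy1, which dendritic epidermal T cells and other cells express, fell from 16.0 ± 2.90 to 9.29 ± 1.90 CPM (adjusted p = 0.00983). That list missed the threshold with library totals or upper-quartile factors (adjusted p = 0.0516 and 0.0512, over alternatives 2.53e-07 to 0.132). Gamma delta T cell markers had 3 of 6 higher and 0 lower (4 and 0 adjusted over the list alone) and were not past the threshold (camera adjusted p = 0.0806). They were past it without CTR 2 (0.0353), CTR 3 (0.0456) or SKO 4 (0.0309), with no count filter (0.000171) and with Xist as a further term (0.0271), with 0.000171 to 0.158 over alternatives. Macrophage and monocyte markers had 2 of 9 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.144). The protease gene Ctss was 2.23-fold higher. Of 6 neutrophil markers, S100a8, S100a9 and Mmp9 rose (3 up and 1 down adjusted over the list alone, camera adjusted p = 0.209), genes that stressed keratinocytes also express. Mean log2 CPM per library of the T cell, gamma delta T cell, Langerhans cell and macrophage lists was higher in SKO by 0.869, 0.919, 0.409 and 0.538. For each list every SKO library was above every CTR library (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0905 over 19 measures, n = 4 per group).

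**Figure D2:**
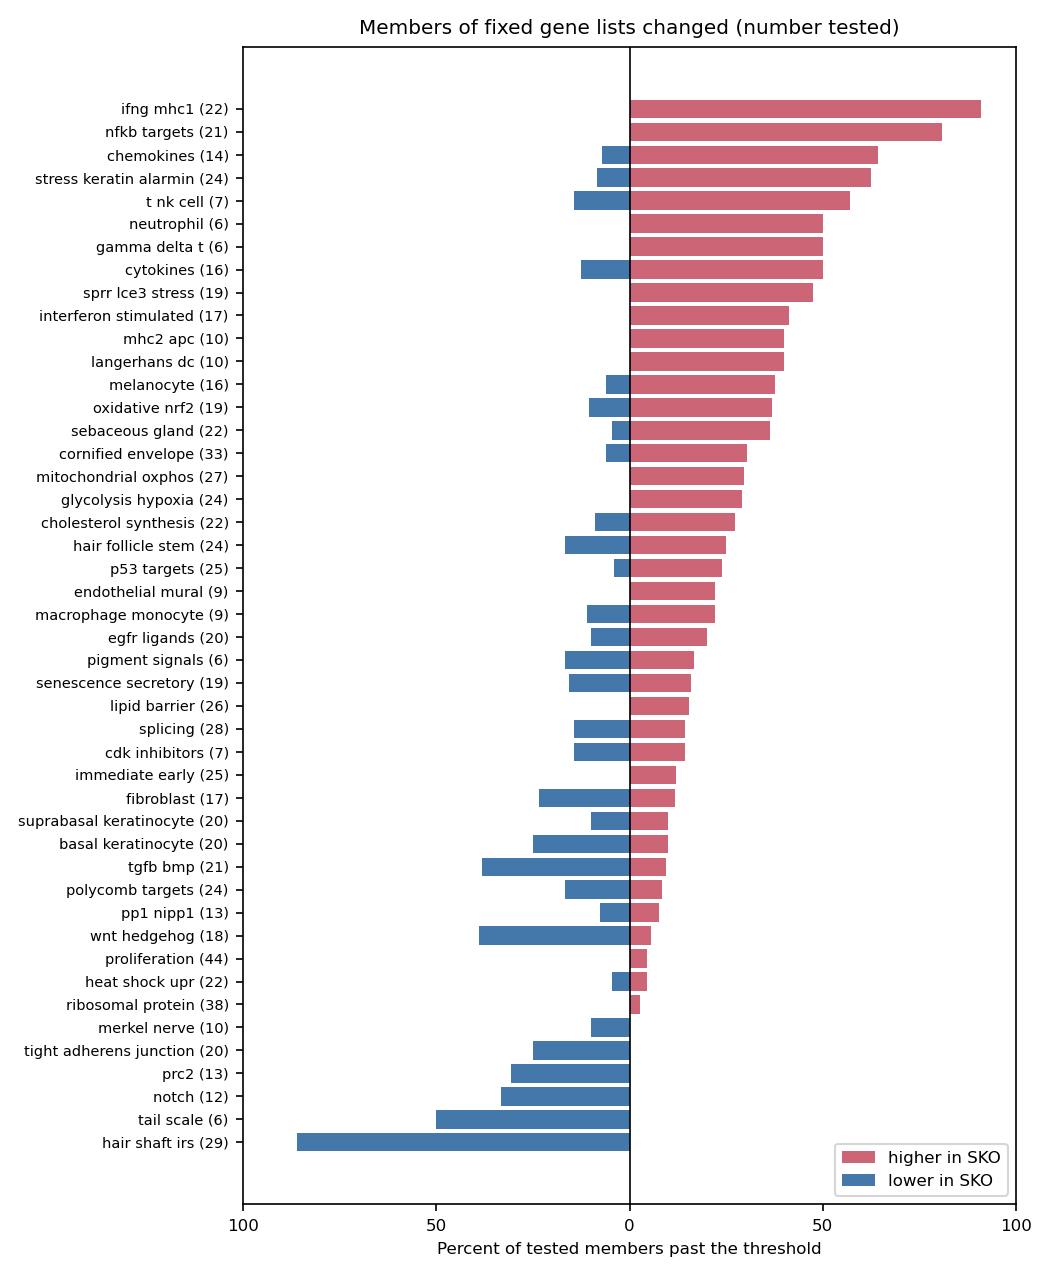
Percent of the tested members of each gene list that passed the threshold (edgeR quasi-likelihood test, adjusted p under 0.05), with members higher in SKO to the right and members lower in SKO to the left, and the number tested in parentheses. The interferon-gamma and MHC class I list (20 of 22 higher) and the hair shaft list (25 of 29 lower) lie at the ends.

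Hair shaft genes were lower in SKO. Of 29 genes of the hair shaft and inner root sheath, 25 fell and 0 rose (29 and 0 adjusted over the list alone). The median log2 fold change was -2.27 (camera adjusted p = 9.91e-12, adjusted p = 0.438 with an estimated correlation). The hair keratin gene Krt33b fell from 493 ± 149.7 to 53.1 ± 53.6 CPM and Krt34 from 462 ± 146 to 57.0 ± 51.4 CPM (adjusted p = 0.0105 and 0.00984). Krt81 fell from 522 ± 167 to 64.6 ± 60.5 CPM and Krtap8-1 from 1320 ± 375 to 133 ± 109 CPM (adjusted p = 0.0104 and 0.00315). All 57 tested Krtap genes had lower means in SKO, 56 of them past the threshold, with a median log2 fold change of -2.96. Krtap transcripts took 1.66% ± 0.325 of counts in CTR and 0.376% ± 0.193 in SKO (exact permutation p = 0.0286, adjusted p = 0.0905, n = 4 per group). Without SKO 3 the log2 fold changes of Krt33b, Krt34 and Krt81 were -4.06, -3.65 and -3.75, in place of -3.21, -3.02 and -3.01. Those of Krt86, Krt31 and Krtap8-1 were then -3.68, -3.60 and -3.99, in place of -2.93, -2.83 and -3.32. Of 6 hard keratin genes of tail scales, Krt31, Krt34 and Krt86, which hair also expresses, fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0317, adjusted p = 0.438 with an estimated correlation). With no count filter that list was not past the threshold (adjusted p = 0.0608, over alternatives 0.0148 to 0.406). In the robust fit the calls of Krt86 and Krt31 ended (adjusted p = 0.0571 and 0.0692, over alternatives up to 0.759 and 0.824). The hair keratin falls shrank with Xist as a further term. Krt33b went to -0.71 (SE 0.63, against 0.71 without the term), Krt34 to -0.64, Krt81 to -0.62, Krt86 to -0.44, Krt31 to -0.38 and Krtap8-1 to -1.35, with 0 of these calls kept. With the same term, neither the hair shaft list nor the Wnt and hedgehog list described next was past it (adjusted p = 0.119 and 0.534). These were the highest values over alternatives at the preset correlation, and the lowest were 5.3e-16 and 0.000307.

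Of 18 Wnt and hedgehog target and feedback genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.00462, adjusted p = 0.438 with an estimated correlation). Hhip fell most, and the Wnt transcription factor gene Lef1 fell from 27.1 ± 6.40 to 6.76 ± 3.66 CPM (adjusted p = 0.00395). The Wnt antagonist genes Nkd1 and Nkd2 were 3.09-fold and 4.62-fold lower (adjusted p = 0.00223 and 0.00771), and Nkd2 changed by -0.68 on the log2 scale with the Xist term in place of -2.21. In SKO 1 to 4 Lef1 had 2.94, 9.56, 10.2 and 4.34 CPM and Nkd2 2.57, 13.9, 13.1 and 3.65 CPM. Both were lower in SKO 1 and SKO 4 than in SKO 2 and SKO 3, as Krt33b was. Hhip had another order (0.524, 1.06, 2.35 and 1.48 CPM). Whether these falls follow the amount of hair follicle in the sheet was not tested. TGF-beta and BMP pathway genes had 8 of 21 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.142). The BMP antagonist gene Fst rose 2.75-fold and the activin subunit gene Inhbb 1.95-fold (adjusted p = 0.000693 and 0.00873). Bambi and Bmp4 were 2.90-fold and 2.38-fold lower (adjusted p = 0.00312 and 0.0152), but with the Xist term neither call held and their log2 fold changes were -0.85 and 0.04. Notch pathway genes had 4 of 12 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.247). The ligand gene Jag2 was among them (log2 fold change -0.34), as was Heyl, which was 3.68-fold lower (adjusted p = 0.0344). Follicle stem and progenitor genes moved both ways, 6 of 24 higher and 4 lower, also adjusted over the list alone. The list's median was -0.02, its mean 0.02 and its direction upward (camera adjusted p = 0.904). In this list Ly6a and Krt17 rose (0.97 and 0.83, adjusted p = 0.00165 and 0.00109) and Bmp6 fell (-0.62, adjusted p = 0.00543).

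Some sebaceous gland genes were higher in SKO. Of 22 in all, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.438 with an estimated correlation). Scd3, a fatty acid desaturase gene of sebocytes, rose from 139 ± 68.0 to 472 ± 95.1 CPM and Apoc1 from 155 ± 28.2 to 334 ± 57.2 CPM (adjusted p = 0.00281 and 0.00129). Cholesterol synthesis genes had 6 of 22 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0516). The enzyme genes Lss and Msmo1 were 1.42-fold and 1.37-fold higher and the sterol feedback gene Insig1 1.68-fold lower. That list was past the threshold without CTR 4 (adjusted p = 0.000952), SKO 1 (0.0491) or SKO 3 (0.0450) and with the series of mouse identifiers as a block (0.0479), with 0.000952 to 0.518 over alternatives. Stratum corneum lipid genes had 4 of 26 higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.839), Fa2h among them (1.69-fold). The median of that list was just below 0 and its mean was 0.06. Melanocyte genes had 6 of 16 higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00426, adjusted p = 0.438 with an estimated correlation). The pigment genes Dct and Mlana were 1.72-fold and 1.68-fold higher (adjusted p = 0.0125 and 0.0107). Keratinocyte factors that act on melanocytes had 1 of 6 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.889).

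Genes of the DNA damage response changed in part. Of 25 p53 targets, 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0449, adjusted p = 0.438 with an estimated correlation). The apoptosis gene Pmaip1 rose 4.96-fold and the ectodysplasin receptor gene Eda2r 2.46-fold (adjusted p = 0.00409 and 0.000316). The death receptor gene Fas rose 2.35-fold and Ccng1 1.33-fold (adjusted p = 0.00669 and 0.00581). The list was not past the threshold without CTR 3 (adjusted p = 0.0747), CTR 4 (0.0803) or SKO 2 (0.0564) or with the stricter count filter (0.151), with 0.0182 to 0.185 over alternatives. Of 7 cyclin-dependent kinase inhibitor genes, Cdkn2a rose and Cdkn1c fell (2.48-fold, adjusted p = 0.00847), with 1 up and 2 down adjusted over the list alone. This list's median (0.04) and mean (0.55) were above 0 while camera gave the downward direction (adjusted p = 0.904). Genes of S phase and mitosis had 2 of 44 higher and 0 lower, and 0 of either adjusted over the list alone (camera adjusted p = 0.209). The list was past the threshold upward without CTR 4 (adjusted p = 0.0144) or SKO 3 (0.0450), and downward with Xist as a further term (0.000731), with 0.000731 to 0.814 over alternatives. Senescence-associated secreted factors had 3 of 19 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.889). Mmp9 was 4.31-fold higher and Igfbp5 2.66-fold lower (adjusted p = 0.00111 and 0.0106).

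Polycomb repressive complex 2 genes had 4 of 13 lower and 0 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.457). Its accessory subunit genes Phf19 and Mtf2 were 1.65-fold and 1.33-fold lower (adjusted p = 0.0184 and 0.0125). Ezh2 and Aebp2 of the same complex were 1.21-fold and 1.16-fold lower (adjusted p = 0.033 and 0.037). Developmental transcription factor genes often marked by Polycomb had 4 of 24 lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.465). The hair regulator gene Hoxc13 fell from 183 ± 19.5 to 75.3 ± 22.2 CPM (adjusted p = 0.00182). Splicing genes had 4 of 28 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.904).

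Nuclear genes for oxidative phosphorylation had 8 of 27 higher and 0 lower, also adjusted over the list alone. Their median log2 fold change was 0.22 (camera adjusted p = 0.000547, adjusted p = 0.55 with an estimated correlation), Ndufb8 among them (1.27-fold). Glycolysis and hypoxia genes had 7 of 24 higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.000666, adjusted p = 0.284 with an estimated correlation). Bnip3, Adm and the phosphofructokinase gene Pfkl rose 1.71-, 1.71- and 1.57-fold. NRF2 targets had 7 of 19 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.243). Hmox1 and Nqo1 were 1.67-fold and 1.59-fold higher (adjusted p = 0.00142 and 0.00272). Heat shock and unfolded protein response genes had 1 of 22 higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.627, median 0.05 and mean -0.02). Chac1 was 3.36-fold lower (adjusted p = 0.00107). Immediate early genes, which respond to tissue handling, had 3 of 25 higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.438 with an estimated correlation), Ier3 among them (1.68-fold). That call ended without CTR 1 (0.0946), CTR 4 (0.0565), SKO 2 (0.0564) or SKO 3 (0.0530), with GC content removed (0.103) and with the stricter count filter (0.179), with adjusted p = 0.00626 to 0.179 over alternatives. Ribosomal protein genes had 1 of 38 higher and 0 lower, and 0 of either adjusted over the list alone (camera adjusted p = 0.229). The ribosomal list was past the threshold, downward, without CTR 2 (0.0274) or SKO 1 (0.00205) and with Xist as a further term (9.78e-11), with adjusted p = 9.78e-11 to 0.973 over alternatives.

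Markers of dermal and other cells showed no common direction. Fibroblast genes had 4 of 17 lower and 2 higher (4 and 3 adjusted over the list alone, camera adjusted p = 0.68). Fn1 was 2.06-fold lower, and Vim, which many cell types express, was 2.37-fold higher (adjusted p = 0.000929). With the Xist term neither call held, and the log2 fold changes were 0.01 for Fn1 and 0.79 for Vim. Endothelial and mural genes had 2 of 9 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.904). Merkel cell and nerve genes had 1 of 10 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.501). Lists with under 5 tested genes were only counted, and their counts were the same adjusted over the list alone. In these, 1 of 3 B and plasma cell genes rose and 1 fell, 1 of 2 red blood cell genes fell, and 0 of 1 mast cell, basophil and eosinophil genes changed. Of 2 muscle and adipocyte genes 1 rose and 1, Fabp4, was 6.72-fold lower (log2 fold change -2.75, and -3.34 without SKO 3). Fabp4 was also the 1 sebaceous list gene that fell. With the Xist term it changed by -1.12 and its call ended (adjusted p = 0.201). Of the genes that mark an animal's sex, Xist was the only one tested, and 4 Y-linked genes had 0 counts in all 8 libraries. Counted over all 46 tested lists, 22 were past the threshold, 17 higher and 5 lower, 0 were past it with an estimated correlation, and 23 were by fry. By fry the cornified envelope, oxidative phosphorylation and immediate early lists missed the threshold (fry adjusted p = 0.101, 0.054 and 0.0512). The neutrophil, macrophage and NRF2 lists were past it upward and the Polycomb complex list downward (fry adjusted p = 0.0136, 0.0289, 0.0289 and 0.0217). With Xist as a further term, the junction and oxidative phosphorylation lists also missed the threshold (adjusted p = 0.903 and 0.47, over alternatives 0.000821 to 0.903 and 5.31e-05 to 0.47). The direction of the oxidative phosphorylation list was then downward. The basal, p53, T cell, tail scale and immediate early lists missed it too. Besides the gamma delta T cell, proliferation and ribosomal lists described above, the EGFR list was then past it, upward (adjusted p = 0.000837, over alternatives 0.000837 to 0.987). Macrophage and monocyte markers were past it with no count filter (adjusted p = 0.00139, over alternatives 0.00139 to 0.264). The 10 most abundant genes took 11.1% ± 0.799 of counts in CTR and 12.8% ± 1.34 in SKO (exact permutation p = 0.0857, adjusted p = 0.204, n = 4 per group).

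**Figure D3:**
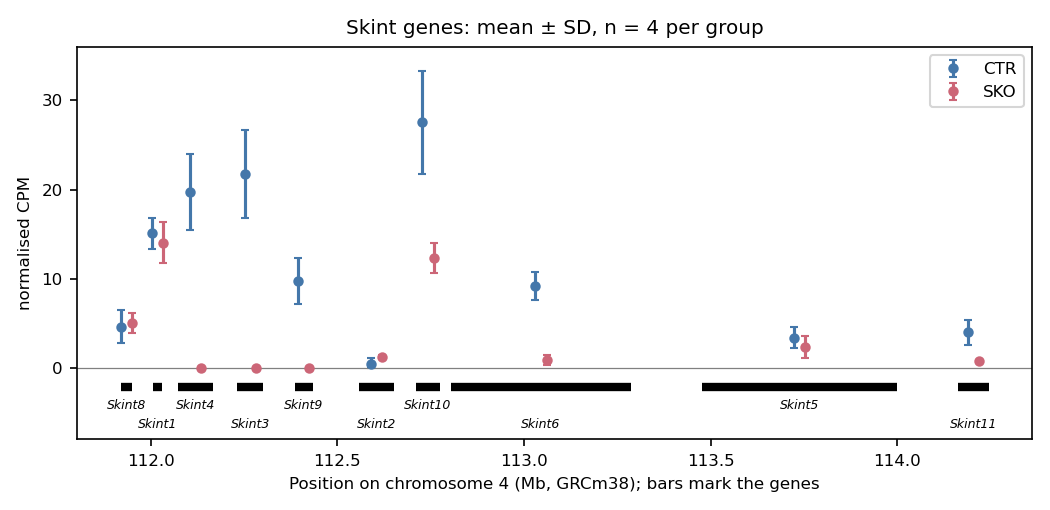
Normalised CPM (mean ± SD, n = 4 per group) of the Skint genes along chromosome 4 (position in Mb, GRCm38), with black bars marking each gene. Skint4, Skint3 and Skint9 lie next to one another at 112.07, 112.23 and 112.39 Mb and are at or near 0 in SKO, about 20 Mb from Ppp1r8.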

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

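Each group of 4 libraries was checked for a library far from the others, for 129 named genes and 19 library measures. In 18 of 294 groups checked the gap between 1 library and its nearest neighbour exceeded Dixon's 95% critical value for that share of the group's range, against 14.7 expected by chance, so this number says little by itself. CTR 3 stood above the other CTR libraries for S100a8 (9.59 CPM against 3.12 to 3.61), S100a9 (6.0 against 1.64 to 2.36), Igfbp3 (204 against 101.1 to 117), Scd3 (240.0 against 90.7 to 115) and Ier3 (70.7 against 50.1 to 53.1). CTR 1 stood above its group for Lif (2.36 CPM against 1.30 to 1.41) and CTR 4 for Lce3e (0.659 against 0.241 to 0.256). SKO 4 was highest of its group for Pglyrp2 (9.53 CPM against 7.33 to 7.71) and Apoc1 (419 against 296 to 315) and lowest for Ereg (61.8 against 82.2 to 85.9). SKO 2 was highest for Ldhb (31.3 CPM against 22.8 to 23.7) and Mtf2 (39.1 against 34.9 to 35.2), SKO 3 lowest for Ndufb8 (76.2 against 92.4 to 93.9), and SKO 1 highest for Coro1a (7.60 against 4.70 to 4.98). SKO 1 also held the only Skint4 count of its group (0.052 CPM against 0). Of the library measures, the share of counts in the 10 most abundant genes was lowest in CTR 2 (9.93% against 11.4% to 11.6%). Mean log2 CPM of fibroblast markers was highest in SKO 4 (2.50 against 2.03 to 2.09), as was that of endothelial and mural markers (0.28 against -0.73 to -0.56). Leaving out the library concerned ended the call of none of these genes.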

How the results depend on the processing

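Dsg4, Tchh, Heyl, Ezh2 and Aebp2, also named, were not checked over the alternatives. Of 122 other named genes past the threshold, 17 stayed past it in every alternative tested, and the term for Xist accounts for all of the rest. With that term 103 of the 122 lost their call and Bmp4 (0.036) and Fn1 (0.013) turned sign, 80 genes changed and 58 changed by at least 2-fold; all libraries had 0 Y-linked counts, so Xist does not separate sexes here, and 73.3% of the variance of its level lay between the groups. For the 103 lost calls, Xist itself among them, a median of 78.1% of the log2 fold change was left and the standard error was 1.81 times as large at the median, and 56 kept at least 75% of their log2 fold change and 22 under 50%. The loss of the Xist call was fixed in advance, since its own level was the term. Over all 3700 called genes a median of 69.5% was left. Of these, 1699 kept at least 75% and 1319 under 50%, among them 217 that turned sign. The term thus lowered both precision and, for part of the genes, the difference. Xist was itself lower in SKO, so the term can also take out part of a genotype difference. In SKO 1 to 4 it followed Krt33b (Xist 330, 436, 574 and 337 CPM, Krt33b 9.38, 65.5, 124 and 13.7 CPM). A call lost with the term therefore cannot be assigned to the genotype or to another source. Krt10 went from 0.99 (SE 0.11) to 0.99 (SE 0.22) and Hhip from -4.51 (SE 0.43) to -4.23 (SE 0.77), but Krt33b from -3.21 (SE 0.71) to -0.71 (SE 0.63). The 22 were Xist, Krt33b, Krt34, Krt81, Krt86, Krt31, Krtap8-1, Krtap28-13, Lef1, Nkd2, Fabp4, Igfbp3, Ifitm3, Cxcl1, Ccl20, Lif, Slpi, Chac1, Ndufb8, Arhgdib, mt-Nd5 and mt-Co1. The stricter count filter left 426 genes changed by at least 2-fold, with fewer genes tested, 11630 against 15638. At an adjusted p under 0.01, 1465 genes changed, and in a test against a fold change of 1.5, 503 did. With an estimated correlation 0 lists were past the threshold. Leaving out each library gave 2589 to 4370 changed genes, 895 to 1151 changed by at least 2-fold, 20 to 24 lists and a Ppp1r8 log2 fold change of -0.21 to 0.048, turned only without SKO 2 (0.048). Of the named genes, Skint8 turned sign without CTR 1 (-0.019), CTR 4 (-0.056) or SKO 2 (-0.011), in a range of -0.056 to 0.32, and mt-Rnr2 without CTR 4, in a range of -0.25 to 0.041, none past the threshold; the cause was not tested. Calls of Cdc5l, Fgf18, mt-Co1, mt-Nd5 and Ppp1cc ended in some of these fits, and Igfbp3, Krt31 and Krt86 lost theirs in the robust fit. The other normalizations, the other tests, no count filter, GC content and the series of mouse identifiers as a block gave 3622 to 4439 changed genes, of which 3233 to 3685 were shared with the 3700, and left every other named call in place. Chosen after seeing the data, leaving out genes within 25 Mb of Ppp1r8 left 3520 and 956, and leaving out hair keratin and Krtap genes left 930 changed by at least 2-fold. Depth limits genes of few counts most, such as Cdkn2a and Defb5 with 8 CTR counts each.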

Other observations

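The tests of explanations, the share of mitochondrial counts and the genes outside the naming rule were chosen after the values were seen; the list tests, the refits without a library and those over other splits were planned. Some transcripts of the mitochondrial genome were lower, while 8 of 27 nuclear genes of oxidative phosphorylation rose and 0 fell (camera adjusted p = 0.000547, adjusted p = 0.55 with an estimated correlation, fry adjusted p = 0.054). Of 11 tested mitochondrial genes, 6 were lower and 0 higher in SKO, among them mt-Nd2 (from 732 ± 52.9 to 457 ± 44.8 CPM, log2 fold change -0.68, adjusted p = 0.00123), mt-Nd5 (-0.62, adjusted p = 0.0209, and 0.0556 without CTR 1) and mt-Co1 (-0.41, adjusted p = 0.03). The mt-Co1 call ended without CTR 1, CTR 2, CTR 3, SKO 1, SKO 2 or SKO 4 (adjusted p = 0.0551 to 0.0812). With Xist as a further term mt-Nd5 changed by -0.04, mt-Co1 by -0.06 and mt-Nd2 by -0.63, and 0 of the 3 were past the threshold. The ribosomal transcript mt-Rnr2 differed by -0.15 (adjusted p = 0.523). All mitochondrial transcripts together took 1.19% ± 0.0511 of counts in CTR and 0.882% ± 0.0833 in SKO (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0905 over 19 measures, n = 4 per group), and the contrast with the nuclear list was not itself tested.

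The abundant hard keratins of tail scales varied widely between SKO libraries. Krt84 had 26447 ± 4005 CPM in CTR and 18482 ± 10132 CPM in SKO (log2 fold change -0.52, SE 0.35, adjusted p = 0.312), and Krt36 20047 ± 2935 and 13916 ± 7879 CPM (-0.53, SE 0.36, adjusted p = 0.318). Single SKO libraries ranged from 7166 to 30010 CPM for Krt84. T cell genes of low level rose, Cd3e from 0.160 ± 0.0847 to 0.888 ± 0.315 CPM and the gamma delta receptor gene Trdc from 0.284 ± 0.186 to 1.44 ± 0.540 CPM (adjusted p = 0.00407 and 0.00725).

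The refits over the 35 ways to split the 8 libraries into 4 and 4 were planned. Only 1 of 35 splits, the real one, gave as many as 3700 changed genes (highest other 2), 1 of 35 as many as 1006 changed by at least 2-fold (highest other 2), and 1 of 35 as many as 22 lists (highest other 19). The real split thus ranked first for the 3 counts, and with 35 splits no rank can be rarer than 1 of 35. All other splits put CTR and SKO libraries together, so the group difference adds to their spread within a group. Their low numbers of changed genes therefore do not show what chance alone would give. For the number of lists, splits that mix the groups came close, and 0 lists were past the threshold with an estimated correlation. The refits by themselves do not exclude chance.

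Skint3, Skint4 and Skint9 were the only 3 of 15638 tested genes with at least 1 CPM in every library of one group and under 0.1 CPM in every library of the other. Reads counted for other Skint copies instead cannot account for this as a whole. All Skint genes summed to 32.5% of the CTR mean in SKO. The flanking Skint1 (-0.10, adjusted p = 0.612) and Skint8 (0.12, adjusted p = 0.784) showed no gain. Skint2 rose at a low level without passing the threshold (1.49, adjusted p = 0.104), and Skint10, Skint6 and Skint11 fell (-1.16, -3.36 and -2.47). Reads dropped because they match several copies would lower the sum too, so such a loss at Skint3, Skint4 and Skint9 is not excluded. A hypothesis is that a strain haplotype linked to the targeted Ppp1r8 alleles may lack or mask these genes, because both Ppp1r8 copies of SKO mice and 1 copy of CTR mice are engineered and the genes lie about 20 Mb away. In its test, the share of genes at p under 0.0001 within 25 Mb of Ppp1r8, Skint genes left out, was 4.75%, against a median of 3.44% over equally long runs of genes on other chromosomes, and 92.3% of runs had a lower share (90.3% for genes at adjusted p under 0.05). This and an effect of genotype on the genes cannot be told apart here, since any linked haplotype goes with the genotype.

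For the lower hair shaft genes, a joint loss of follicle and sebaceous tissue from the peeled sheet would lower the sebaceous gland list about as much. That list's median log2 fold change was 0.26 (95% interval -0.10 to 0.75), against -2.27 for hair shaft genes. Loss of bulge and junctional follicle cells would lower their markers alike, and the median of 9 such genes was -0.082 (95% interval -0.23 to 0.20), with 1 of them, Fgf18, lower (-0.91, adjusted p = 0.0199, and 0.0525 to 0.0537 without CTR 1 or CTR 4). Some of these 9 markers are also expressed outside the bulge, which would dilute a loss. They were chosen after the values were seen and leave out Bmp6, a follicle stem list gene that fell (-0.62, adjusted p = 0.00543). Of all 24 genes of that list, 6 rose and 4 fell. The median of the 9 thus does not decide on such a loss. Loss of follicle parts without sebaceous gland stays open, since the sebaceous list does not report on them. A difference in hair cycle stage or in hair shaft formation between the genotypes also stays open, and none of these was tested.

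For the higher immune genes, more leukocytes of the same mix would raise general leukocyte genes as much as the interferon-gamma and MHC class I list. The median of 13 general leukocyte genes was 0.82 (95% interval 0.29 to 1.26). Cd52, Coro1a and Arhgdib were higher (1.52, 1.26 and 0.82) and Ptprc was not past the threshold (0.87, adjusted p = 0.0709). The median of the interferon-gamma list was 1.08 (95% interval 0.65 to 1.53). The intervals overlap, so more leukocytes and a stronger response per cell cannot be told apart here. Handling of the tissue was taken to raise immediate early genes at least as much as NF-kappaB targets. The median of the immediate early genes was 0.21 (95% interval 0.03 to 0.32) and that of the NF-kappaB targets 0.68 (0.33 to 0.97). Immediate early genes thus rose less, but how the 5 h in dispase would move the 2 lists was not tested. These values therefore do not decide on handling. More leukocytes and a keratinocyte response also remain candidate explanations.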
